A study of Mus musculus with 18 samples.

How the data were processed

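RNA from 18 samples of sorted mouse cells was measured on Affymetrix arrays, 3 arrays in each of 6 groups. Per the labels, Lck-Cre mice received bone marrow infected with a retrovirus that carries NPM-ALK, the fusion kinase of anaplastic large cell lymphoma, and lymphomas of the thymus were taken when the mice were moribund. The series design names 3 lymphomas, whose cells were sorted into a common lymphoid progenitor fraction (CLP) and the double-negative fractions DN1, DN2, DN3 and DN4. LSK cells (lineage-negative, SCA1-positive, KIT-positive) were sorted from bone marrow of healthy mice that were 18 months old. The sort used CD4, CD8, CD25, CD44, IL7Rα, KIT, SCA1 and lineage markers on a MoFlo XDP instrument, and the lineage markers are not named in the sources used here. RNA was extracted with the RNeasy Micro kit and amplified with the WT Pico kit.

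The deposited values are log2 RMA signals, 1 per probe set, made by the authors with the oligo package (versions not given in the sources used here). They were taken as they are. The table holds 41345 probe sets with 0 missing values. Of these, 23521 carry 1 gene symbol, 1814 carry several symbols and 16010 carry none. The last 2 kinds, 17824 probe sets, were left out of the gene tests, since their signal cannot be given to 1 gene. The brightest probe set stood for each gene, judged by the mean over all 18 arrays, which left 22180 genes. No genome build is given in the sources used here, so genes are placed by chromosome only. Among 1082 genes with several probe sets, 11 had called probe sets of opposite sign between all lymphoma fractions and LSK.

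Each comparison was tested with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg over all genes tested, adjusted p under 0.05). The comparison of all lymphoma fractions with LSK used the mean of the 5 fraction arrays of each replicate number, hence 3 values against 3 LSK arrays. Each comparison of 1 fraction with LSK used the 3 arrays of that fraction and the 3 LSK arrays. Differences among fractions came from 1 model of the 15 lymphoma arrays, with an F test for any difference and contrasts for pairs of fractions and for CLP against the mean of DN1 to DN4. All p values of single genes in the text are adjusted p values from limma. SE is the limma standard error of the difference. A gene list was tested with camera (preset correlation between genes of 0.01, and again with a correlation estimated from the residuals) and with fry. Camera asks whether a list moved more than the other genes, and fry asks whether the members of a list moved at all. Both were adjusted over the 19 lists of a comparison. The fixed lists are sort markers, stem and multipotent progenitor genes, T lineage genes, TCR rearrangement and pre-TCR genes, Notch pathway targets, NPM-ALK and STAT3 linked genes, cytotoxic and NK genes, T cell activation and checkpoint genes, cell cycle genes, quiescence and p53 target genes, glycolysis and hypoxia genes, type I interferon response genes, MHC class II genes, and markers of B cells, macrophages and monocytes, granulocytes, erythroid cells and megakaryocytes, dendritic cells, and stroma and thymic epithelium. List counts are given over all genes, and for the lists described at length again with p values adjusted over the list alone where these differ.

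The groups, tests, lists, thresholds, named-gene rule and the alternatives below were chosen before the data were examined. Named genes are the 10 called genes with the largest rise and the 10 with the largest fall among those without overlap between the groups, and up to 4 members of each list with the smallest p. Predicted and clone-named genes, small RNA genes, olfactory and pheromone receptors and antigen receptor segments were left out of the ranking by size. For the F test the 10 genes with the smallest p are named. The exceptions, named after their values were seen, are Alk, Npm1, Xist, Eif2s3y and the receptor gene segments, which were looked at for what the labels say about the model, for the sex of the mice and for the immunoglobulin signal in DN1. Vim, Ifitm3 and Xbp1, and Slamf1 against LSK, were also named after their values were seen. Genes of the sort markers check the labels and are no finding.

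The alternatives were a filter for genes above the array median in at least 3 arrays, quantile normalization, the mean of the probe sets of a gene, a trended and robust prior, the replicate number as a block, all 18 arrays in 1 model and leaving out each replicate array in turn. Lists were tested again with the filter, with the estimated correlation and with the block. Chosen after the data were seen were the lymphoma mean without each fraction, the LSK comparisons without genes on X and Y, the F test without CLP, and the Notch and STAT3 lists without genes that are also sort markers. Olfactory receptor genes, which are largely silent in blood cells, were taken after the data were seen as a gauge of background.

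The code was tested on simulated data with the same groups and, for each gene, a spread averaged over the groups. Genes and arrays were drawn independently, so the larger spread of CLP and any correlation between fractions or genes are absent. For all fractions against LSK it called 84% of genes shifted by log2 1 and 98% of genes shifted by log2 2. For DN4 against DN3 these shares were 74% and 99%. Camera called 11 of 11 shifted lists and 1 of 11 unshifted lists, which does not test lists whose genes correlate. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.

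Same-number arrays deviate from their group means together (r over 0.1 in all 3 pairs) for DN2 with DN3 (0.139 to 0.259), DN3 with DN4 (0.108 to 0.273) and DN1 with DN4 (0.121 to 0.135), so these comparisons were taken as paired by number. The numbers do not always single out a pair. DN3 array 2 correlates more with DN4 array 1 (0.166) than with DN4 array 2 (0.108). DN1 array 2 does so about equally (0.122 and 0.121). DN1 with DN3, a pair not compared here, also passes (0.116 to 0.235). The pairing comes from the data and not from the labels. Results of the fit with the replicate number as a block are given where they change the call of a named gene or of a list.

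Genes of the lists without a probe set of their own were left out, among them Ly6a, Lck, Tcf7, Trac, Trbc1, Rag1 and Cd74. Overlap between comparisons that share arrays was not counted.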

Results

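The 15 arrays of lymphoma cells and the 3 arrays of healthy LSK cells separate along the main axis of the data. Principal component 1 holds 50.7% of the variance and places the LSK arrays at 86.22 to 91.25 and the lymphoma arrays at -24.46 to -5.23. Component 2 holds 13% and orders the fractions, with DN1 at -39.89 to -35.61, DN2 at -18.11 to -15.1, and CLP, DN3 and DN4 together at 8.34 to 18.74. Arrays of the same group correlate with r between 0.933 and 0.987. The CLP arrays are the least alike (r of 0.933 to 0.945, median SD over genes 0.235), against 0.985 to 0.987 and a median SD of 0.138 in DN2. They correlate less with each other (mean r 0.937) than with the arrays of DN2 (0.954), DN3 (0.956) and DN4 (0.955).

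**Figure D1:**
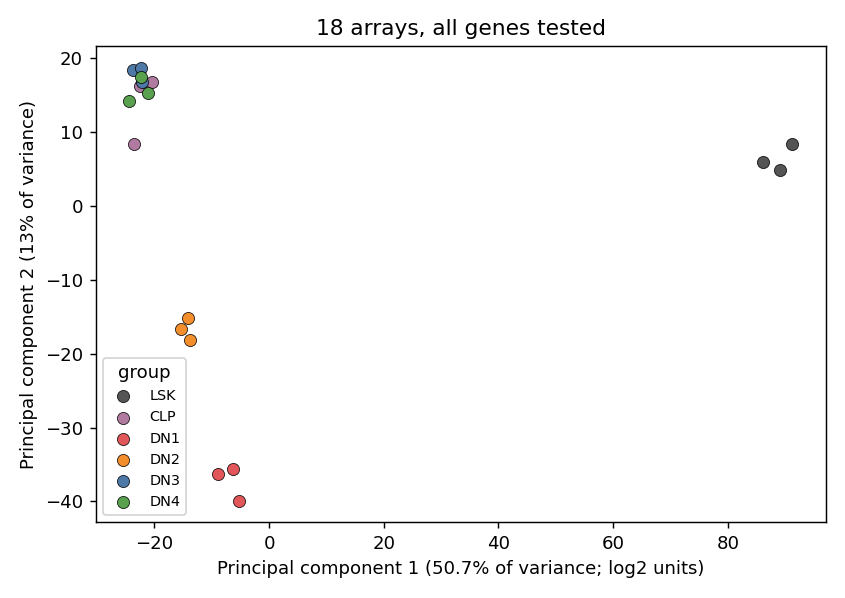
Principal components of the 18 arrays over all genes, with component 1 on the x axis (50.7% of the variance) and component 2 on the y axis (13%), both in units of log2 signal. Each point is 1 array, coloured by group (CLP, DN1, DN2, DN3, DN4 and LSK, 3 arrays each).

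The genes of the sort markers were read as a check of the labels. Il2ra, which encodes CD25, averages 11.81 (SD 0.05, n = 3) in DN2 and 12.02 (SD 0.138) in DN3, against 9.04 in DN1, 8.71 in DN4 and 8.31 in CLP. Kit is at 10.77 in DN1 and 10.68 in DN2, and at 8.06 in DN3 and 8.20 in DN4. Cd44 is at 6.64 in DN1, 5.945 in DN2, 4.67 in DN3 and 4.70 in DN4. These levels mostly follow the usual surface definition of the DN stages, though Cd44 is lower in DN2 than in DN1 (adjusted p = 0.0235 by limma). Il7r, which encodes IL7Rα, is lowest in CLP among the lymphoma fractions. It is at 7.99 (SD 0.899) in CLP, 8.51 in DN4, 8.64 in DN2, 8.86 in DN3 and 9.75 in DN1, against 6.10 in LSK. The RNA of this marker thus does not bear out the CLP label. LSK cells carry Kit at 10.90, Cd44 at 7.36 and Il2ra at 9.62 (SD 0.466). Cd8a stays between 4.45 and 5.45, near the background of the arrays. Cd4 is at 6.63 in DN1, 6.39 in DN2, 5.93 in DN3, 5.74 in DN4, 5.61 in CLP and 4.95 in LSK, and Cd8b1 is at 8.17 to 8.81 in the lymphoma fractions.

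**Figure D2:**
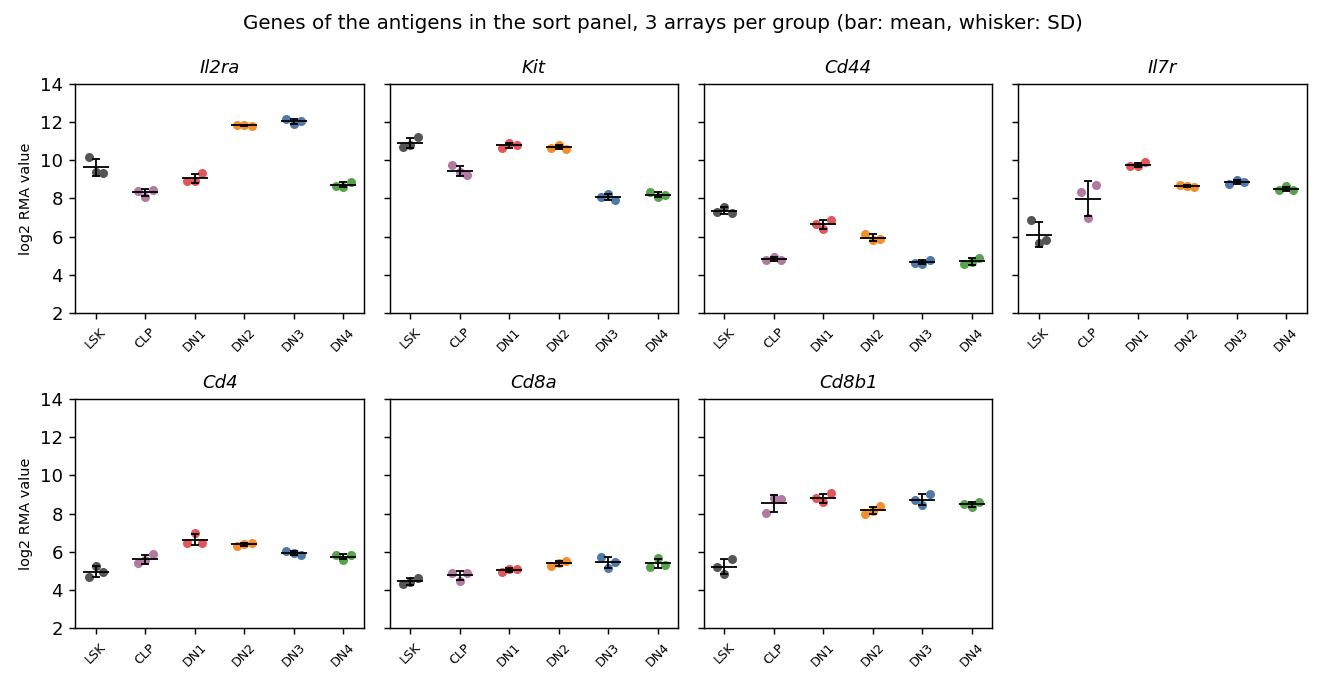
Signal of the genes of 7 sort markers, with the gene and group on the x axis and the log2 RMA signal on the y axis. Points are single arrays (3 per group of CLP, DN1, DN2, DN3, DN4 and LSK), bars the group mean and whiskers the SD.

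Several label facts bear on all that follows. The description fields name aged NIPA knockout or wild-type mice, for 12 arrays with a dose of 4 Gy, which conflicts with the genotype fields and the sample titles, and the titles were followed here. Labels do not say whether arrays of 1 replicate number come from 1 animal across fractions. LSK and lymphoma cells also differ in tissue (bone marrow and thymus) and in the stated age of 18 months for LSK, and they may differ in batch. Xist, the RNA of the inactive X chromosome, reads 3.55, 10.74 and 10 on LSK arrays 1, 2 and 3, and the Y-linked gene Eif2s3y reads 8.42, 7.43 and 4.69. In the lymphoma groups Eif2s3y averages 8.95 to 9.20 and Xist 3.83 to 4.69. By these genes the lymphoma groups and LSK array 1 read as male and LSK array 3 as female, while LSK array 2 carries both RNAs. LSK arrays 2 and 3 thus differ from the lymphoma groups in sex-linked RNA, and the labels do not give the sex. With 3 arrays per group the number of arrays limits precision, and signals below about 5.36 to 5.71, the range over arrays of the 95th percentile of olfactory receptor probe sets, are not told apart from background. Where the lower of a pair of levels lies there, as for Cd3g and Gzma in LSK, Cd34, Adgrl4 and Mpo in the lymphoma, Jchain in DN2 and Moxd1 in DN3 and DN4, the printed log2 difference depends on the floor of the probe set and is not an exact fold.

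Lymphoma cells as a whole express a T cell program that LSK cells lack, and lack the stem and progenitor program of LSK cells. Cd3g (probe set 17526456, chromosome 9), a chain of the CD3 complex of the T cell receptor, is higher by log2 7.75 (SE 0.164, adjusted p = 3.62e-09, 3 against 3 values), at a mean of 12.39 against 4.63. Cd3e (log2 7.50), Cd3d (6.46) and Themis (4.57), which acts in thymocyte selection, rose with it. All 21 measured T lineage genes were higher, also when adjusted over the list alone (camera adjusted p = 3.52e-23, and adjusted p = 0.00526 with an estimated correlation). Of 6 TCR rearrangement and pre-TCR genes all 6 were higher, among them Ptcra, the pre-TCR alpha chain (2.11), Dntt, the polymerase that adds junctional nucleotides (1.61), and Arpp21 (3.43). Their camera adjusted p = 3.78e-05 became adjusted p = 0.145 with an estimated correlation. The rise is not shared by every fraction. In DN1 alone 3 of the 6 were called against LSK, and Ptcra is at 5.84 there against 5.68 in LSK. Rag2, also among the 6, lies within or below the background range in DN2 (3.67), DN3 (5.07), DN4 (5.46) and LSK (4.02). Fry, which does not compare a list with other genes, also calls the T lineage list (adjusted p = 2.18e-06).

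On the other side Cd34 (probe set 17221014, chromosome 1), a surface glycoprotein of progenitors, is lower (log2 -5.95, SE 0.098, adjusted p = 2.23e-09), at 5.16 against 11.10. Meis1 (probe set 17260815, chromosome 11; log2 -5.90), Erg (-4.13) and Gata2 (-3.73), transcription factors of blood stem cells, fell with it. Of 27 stem and multipotent progenitor genes 23 fell and 1 rose (24 fell and 1 rose when adjusted over the list alone; camera adjusted p = 1.24e-18, and adjusted p = 0.00526 with an estimated correlation). The exception is Slamf1 (2.63), a receptor that T cells also carry. Adgrl4 (probe set 17403605, chromosome 3), an adhesion receptor (log2 -7.03, SE 0.112), also fell to below background, as did Lilrb4a (-6.77), and large falls were seen for Ctla2a (-6.38), Rgs18 (-6.37) and Neurl3 (-6.34). Markers of granulocytes fell in 10 of 15 cases and rose in 0 (13 fell when adjusted over the list alone), led by the neutrophil enzymes Mpo (-5.32) and Elane (-4.88), with Ctsg (-3.27). Erythroid and megakaryocyte markers fell in 6 of 11 cases and rose in 1, among them Car2 (-5.96), Pf4 (-3.34) and Car1 (-2.92). Dendritic cell markers fell in 6 of 12 (7 when adjusted over the list alone), with Flt3 (-4.13), Irf8 (-2.26) and Itgax (-1.68). The camera calls for these 3 marker lists (7.32e-09, 0.00212 and 0.00212) became adjusted p = 0.336, 0.336 and 0.284 with an estimated correlation.

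Genes tied to the disease and to effector T cells moved one by one more than as lists. Tnfrsf8 (probe set 17432687, chromosome 4), which encodes the CD30 antigen of anaplastic large cell lymphoma, is higher (log2 4.82, SE 0.198, adjusted p = 1.14e-07), at 10.2 to 10.55 in the fractions and 5.57 in LSK. Yet of 29 NPM-ALK and STAT3 linked genes 3 rose and 12 fell (5 and 13 when adjusted over the list alone), with Vegfa (-4.14), Cd274, which encodes PD-L1 (-1.57), and the survival gene Bcl2l1 (-1.42) lower. Camera calls this list lower (adjusted p = 0.0464, adjusted p = 0.39 with an estimated correlation and 0.305 with the filter on low values). Alk itself reads 4.84 to 5.11 in the fractions and 4.41 in LSK, below the background range, and Npm1 reads 12.46 to 12.61 against 12.51. Whether these probe sets detect the transcript of the retroviral fusion is not given in the sources used here, so they do not tell whether it is expressed. Gzma (probe set 17296286, chromosome 13), a granule protease of killer cells, rose (log2 7.26, SE 0.164) while 7 of 17 cytotoxic and NK genes fell, among them Ccl5 (-3.52), Klrd1 (-2.00) and Nkg7 (-1.71). That list does not pass (adjusted p = 0.0545). Of 19 T cell activation and checkpoint genes 9 rose, such as Cd160 (1.72), and 7 fell, such as Nr4a2 (-2.32) and Nr4a1 (-1.75), immediate early genes of receptor signalling (10 and 7 when adjusted over the list alone, adjusted p = 0.83, list median 0.26 and mean -0.08).

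Notch pathway targets rose in 8 of 14 cases and fell in 3. Notch3 (probe set 17343299, chromosome 17) rose 12.1-fold (log2 3.59, SE 0.168, adjusted p = 2.75e-07), with its pathway targets Dtx1 (probe set 17452038, chromosome 5; 3.07) and Heyl (2.88). Camera adjusted p = 0.00721 became adjusted p = 0.277 with an estimated correlation. Cell cycle genes rose in 8 of 26 cases and fell in 0 (9 rose when adjusted over the list alone), by modest amounts such as 0.86 for Tyms and 0.84 for Rrm2, both enzymes of nucleotide supply (adjusted p = 0.00721, and adjusted p = 0.599 with an estimated correlation). MHC class II genes fell in 6 of 8 cases, led by H2-Ab1 (-3.35), H2-Aa (-2.86) and H2-DMa (-1.93), while H2-Oa rose (2.44). That list fell (adjusted p = 0.00192), with adjusted p = 0.39 with an estimated correlation, and 7 fell when adjusted over the list alone.

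The remaining lists did not pass against LSK. Quiescence and p53 target genes split into 6 higher, such as Trp53inp1 (1.79), and 3 lower, such as the cyclin kinase inhibitor Cdkn1a (-2.93) and Sesn2 (-1.31), with adjusted p = 0.595, a list median of -0.06 and a positive mean. Glycolysis and hypoxia genes split into 5 higher, such as Egln3 (1.63), and 6 lower, such as Bnip3 (-1.16) and Hk2 (-0.85), with adjusted p = 0.503. Of 14 type I interferon response genes 2 rose, among them Usp18 (1.51), and 6 fell, among them Ifit1 (-1.57) and Rsad2 (-1.40), with adjusted p = 0.197 (3 and 6 when adjusted over the list alone). B cell markers fell in 3 of 14 cases, among them Cd79b (-1.28), with adjusted p = 0.0861 (1 when adjusted over the list alone). Macrophage and monocyte markers fell in 6 of 15, with Csf1r (-2.64), Lyz2 (-2.37) and Cd14 (-2.19), and rose in 3, among them Mrc1, the mannose receptor (1.12), with adjusted p = 0.197. Of 16 stromal and thymic epithelial markers 2 rose, Pdgfrb (probe set 17351027, chromosome 18; log2 4.50, SE 0.172) and Col1a2 (1.06), and 2 fell (1 when adjusted over the list alone; adjusted p = 0.404). Pdgfrb, a receptor kinase, is at 12.14 to 12.61 in every lymphoma fraction and 7.94 in LSK. Sort markers as a list had adjusted p = 0.202. In all, limma called 6425 genes, 2914 higher and 3511 lower, and 1948 of them changed at least 2-fold. All lymphoma values lay to the same side of all LSK values in 44.7% of genes, against 10% by chance.

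Each fraction on its own shows the same outline against LSK. The comparisons share the same LSK arrays, so part of this likeness is built in. All 21 T lineage genes rose and 23 of 27 stem and progenitor genes fell in CLP, DN1, DN2, DN3 and DN4 alike. Cd3g rose by log2 7.86 in CLP, 7.36 in DN1, 7.69 in DN2, 7.97 in DN3 and 7.88 in DN4, and Tnfrsf8 by 4.63 to 4.98. Adgrl4 fell in CLP (-7.24), DN1 (-6.94), DN2 (-6.97) and DN3 (-7.06), and Mpo fell in each fraction. With an estimated correlation the T lineage call holds at adjusted p = 0.0042 (CLP), 0.00723 (DN1), 0.0132 (DN2), 0.00794 (DN3) and 0.00949 (DN4), and the stem and progenitor call at 0.0042, 0.00723, 0.00864, 0.00794 and 0.00949.

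**Figure D3:**
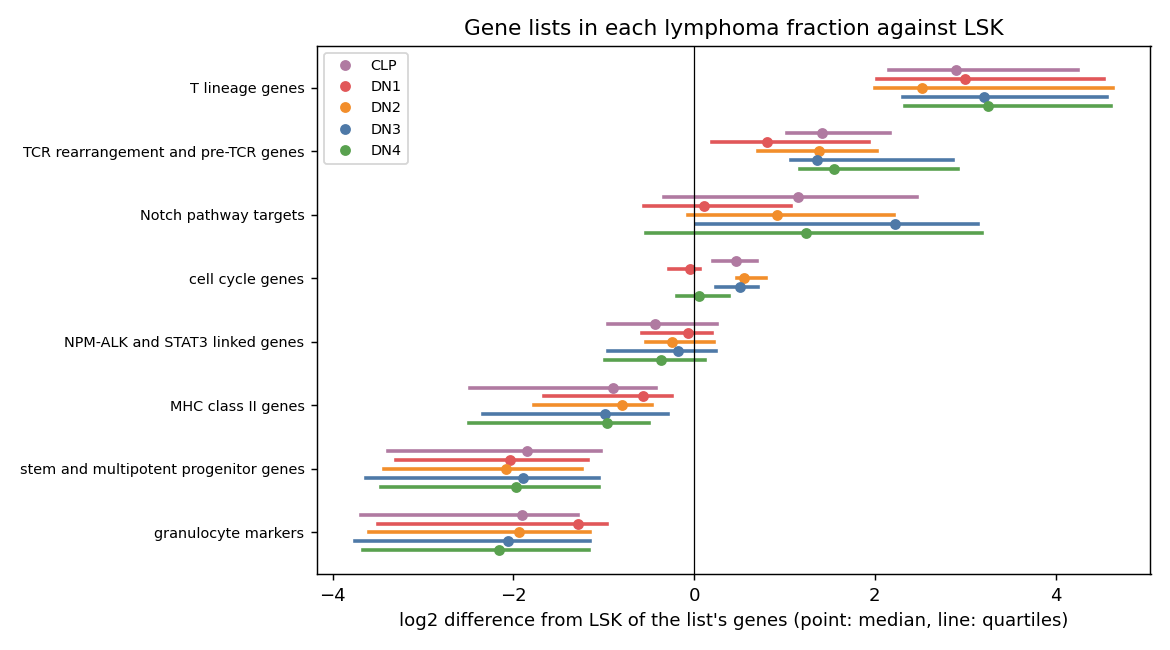
Change of 8 gene lists in the CLP, DN1, DN2, DN3 and DN4 fractions, with the log2 difference from LSK on the x axis and the list on the y axis. Each point is the median over the genes of a list in 1 fraction (3 arrays against 3) and each line spans the quartiles.

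CLP cells against LSK add Upk1b (5.37), Gfra1 (5.35) and Ifi204 (6.48) to the higher genes, with Notch3 at 3.81 and Dtx1 at 3.66. Of 22180 genes 3928 were called, 1451 higher and 2477 lower. Without LSK array 1 that number is 2559, and with all 18 arrays in 1 model it is 6140. No overlap was seen in 36.7% of genes, against 10% by chance. Camera also calls pre-TCR, Notch and cell cycle genes higher, and NPM-ALK and STAT3 linked genes, MHC class II genes and macrophage, granulocyte, erythroid and dendritic markers lower. These calls become adjusted p = 0.0646 (pre-TCR) to adjusted p = 0.544 (cell cycle) with an estimated correlation. The macrophage list has a median of 0.03 and a mean of -0.64. Median and mean also differ in sign for the activation genes and the interferon genes. For the sort markers both are positive while camera points lower. The activation, interferon and sort marker lists do not pass, whereas the macrophage list does (camera adjusted p = 0.0461).

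DN1 cells against LSK add Moxd1, a copper monooxygenase homologue (7.38, SE 0.128), Lrrn3 (6.78), Pcsk1, a prohormone convertase (6.37), and Slc15a1, a peptide transporter (6.35). Mrc1 rose by 2.82. Among 4378 called genes 1652 are higher and 2726 lower (no overlap in 35%, against 10% by chance). The Notch and cell cycle lists do not pass here (adjusted p = 0.425 and 0.516), although Notch3 rose by 1.87. Calls for pre-TCR genes higher and MHC class II, granulocyte, erythroid and dendritic genes lower become adjusted p = 0.223 (pre-TCR) to adjusted p = 0.489 (MHC class II) with an estimated correlation.

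DN2 cells against LSK share Moxd1 (5.65), Slc15a1 (5.36) and Mrc1 (2.43) with DN1 and add Mpzl2 (5.94). Cell cycle genes rose in 17 of 26 cases and fell in 0 (20 rose when adjusted over the list alone), the most of any fraction, with camera adjusted p = 7.7e-08 and adjusted p = 0.361 with an estimated correlation. Of 5638 called genes 2532 are higher and 3106 lower (no overlap in 39.5%, against 10% by chance). The other calls, pre-TCR and Notch genes higher and cytotoxic, MHC class II, B cell, granulocyte, erythroid and dendritic genes lower, become adjusted p = 0.195 (pre-TCR) to adjusted p = 0.456 (B cell) with an estimated correlation.

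In DN3 and DN4 cells Notch3, Dtx1 and Ptcra differ more from LSK than in the other fractions, whereas Dntt does so in DN2 and DN1 (2.24 and 2.15). Notch3 rose by 4.22 and 4.52, Dtx1 by 4.06 and 3.92, and Ptcra by 3.29 and 3.34. H2-Ab1 fell most here, at -4.15 in DN3 and -4.31 in DN4. All 6 pre-TCR genes rose in DN3 and DN4. Of 14 Notch targets 9 rose and 2 fell in DN3 (3 fell when adjusted over the list alone), and 8 rose and 4 fell in DN4. The pre-TCR call becomes adjusted p = 0.0551 (DN3) and 0.118 (DN4) with an estimated correlation, and the Notch call adjusted p = 0.0551 and 0.232. NPM-ALK and STAT3 linked genes fell in 12 (DN3) and 15 (DN4) of 29 cases (13 and 15 when adjusted over the list alone), a call that becomes adjusted p = 0.308 (DN3) and 0.232 (DN4) with an estimated correlation. Remaining camera calls give adjusted p = 0.174 to 0.464 in DN3 and 0.188 to 0.477 in DN4 with an estimated correlation. The macrophage call in DN3 joins a list median of 0.003 to a mean of -0.62. Limma called 5443 genes in DN3 (2539 higher, 2904 lower) and 5908 in DN4 (2612 higher, 3296 lower), with no overlap in 39% and 41.9% of genes.

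The 5 lymphoma fractions are not alike. Moxd1 spans 6.95 log2 units between its highest and lowest fraction, Pde9a, a cGMP phosphodiesterase, 4.86, Fbp1, an enzyme of gluconeogenesis, 4.44, Rhobtb3 4.39, Susd4, a complement regulator, 4.37, and Igfbp4 4.26. An F test called 1748 genes, of which 844 span at least 2-fold. Called genes include 8 of 14 Notch targets, 14 of 26 cell cycle genes, 11 of 21 T lineage genes, 4 of 6 pre-TCR genes, 5 of 8 MHC class II genes and 11 of 29 NPM-ALK and STAT3 linked genes. Among markers of other cells 3 of 14 B cell markers, 2 of 15 granulocyte, 2 of 15 macrophage, 1 of 12 dendritic, 1 of 16 stromal and 0 of 11 erythroid and megakaryocyte markers differ, where 1748 of all 22180 genes do.

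**Figure D4:**
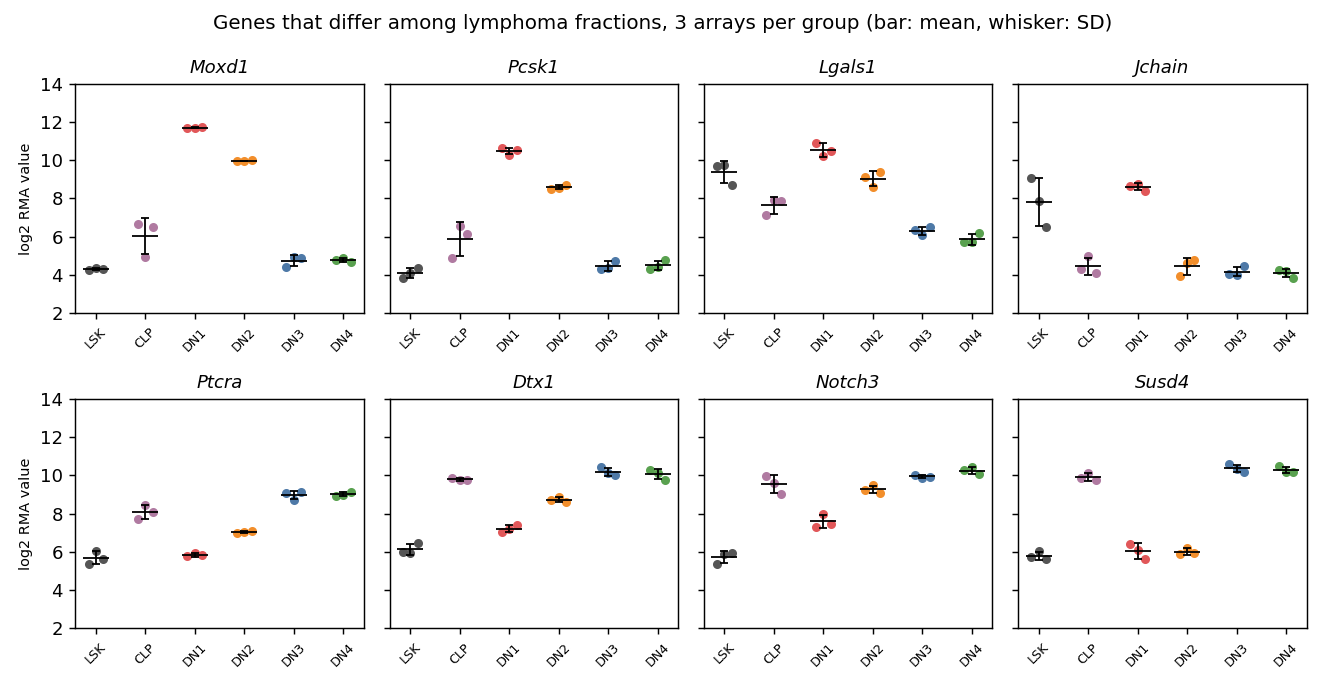
Signal of 8 genes that differ among lymphoma fractions (Moxd1, Pcsk1, Lgals1, Jchain, Ptcra, Dtx1, Notch3 and Susd4), with the group on the x axis and the log2 RMA signal on the y axis. Points are single arrays, 3 per group of CLP, DN1, DN2, DN3, DN4 and LSK.

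From DN1 to DN2 proliferation and Notch genes rise and immunoglobulin genes fall. Jchain (probe set 17449447, chromosome 5), the joining chain of secreted antibody, is lower in DN2 (log2 -4.15, SE 0.234, adjusted p = 2.2e-08), at 4.45, below background, against 8.60 in DN1. Ighm (probe set 17284349, chromosome 12), the mu heavy chain, fell by 2.45. Among 21 immunoglobulin gene segments 16 fell, with a median change of -2.45 (14 and -2.14 without DN2 array 1). Notch3 rose 3.2-fold (log2 1.68, SE 0.209, adjusted p = 0.000344), with Dtx1 (1.51), Ptcra (1.20) and Fbp1 (1.66). Cell cycle genes rose in 9 of 26 cases over all genes and in 23 when adjusted over the list alone, such as the replication helicase gene Mcm5 (1.14), Aurkb (1.13) and Rrm2 (0.92), with 0 falling (camera adjusted p = 7.3e-31, and adjusted p = 0.0347 with an estimated correlation). Of 14 Notch targets 4 rose (7 when adjusted over the list alone; adjusted p = 0.00482 with an estimated correlation). 1 of these is Il2ra, on which the fractions were sorted, and without it 3 of 13 rose (6 when adjusted over the list alone; adjusted p = 0.0326 with an estimated correlation). Without Il2ra, a choice made after the data were seen, the NPM-ALK and STAT3 linked genes are lower by camera (adjusted p = 0.00301, and adjusted p = 0.0326 with an estimated correlation), with 0 of 28 passing one by one and 2 lower when adjusted over the list alone. Also 2 of 6 pre-TCR genes rose (adjusted p = 0.0347 with an estimated correlation).

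Genes that fell from DN1 to DN2 include S100a6, a calcium-binding protein (-2.09), Pcsk1 (-1.90), Il18 (-1.88), Samhd1 (-1.83), Moxd1 (probe set 17232215, chromosome 10; -1.73), Il18r1 (-1.65) and the T cell kinase Txk (-1.46). Activation and checkpoint genes fell in 2 of 19 cases, Cd69 (-1.08) among them (4 when adjusted over the list alone; adjusted p = 0.0347 with an estimated correlation), and MHC class II genes in 2 of 8 (adjusted p = 0.0391 with an estimated correlation). Of 14 B cell markers 1 was lower, Ighm, and 1 higher (2 lower and 1 higher when adjusted over the list alone), and camera calls the list lower (adjusted p = 0.00627, and adjusted p = 0.0549 with an estimated correlation). Granulocyte markers fell in 1 of 15 cases, Lcn2 (-0.96), and 3 when adjusted over the list alone, and cytotoxic genes in 1 of 17 (2 when adjusted over the list alone), calls that become adjusted p = 0.178 and adjusted p = 0.093 with an estimated correlation. No other list passes (adjusted p = 0.0546 to 0.861), and the dendritic list has a median of 0.08 with a mean of -0.001. In total 300 genes were called, 157 higher and 143 lower, 117 of them by at least 2-fold (1736 unadjusted, no overlap in 14.5% of genes against 10% by chance). Without DN2 array 2 the number called is 144, and without DN2 array 3 it is 168.

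From DN2 to DN3 the cells exchange a set of strongly expressed genes. Moxd1 fell to below background (log2 -5.22), with Pcsk1 (-4.12), the mucin gene Muc13 (-3.47), Igfbp4 (-3.09), Tgm2, a transglutaminase (-2.82), Lgals1, which encodes galectin (-2.71), and S100a6 (-2.60). Susd4 (probe set 17220417, chromosome 1) rose 20.6-fold (log2 4.37, SE 0.19, adjusted p = 7.8e-10), with Atp8a2, a lipid flippase (probe set 17307354, chromosome 14; 4.27), Rhobtb3 (probe set 17294458, chromosome 13; 4.02), Pde9a (probe set 17335842, chromosome 17; 3.98), Cpe (3.45), Nfib (3.00) and the cyclin gene Ccnd2 (2.81). Limma called 544 genes, 289 higher and 255 lower (265 by at least 2-fold, 1789 unadjusted, no overlap in 16.2% of genes against 10% by chance).

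Among lists, Notch targets rose in 4 of 14 cases and fell in 1 (6 and 1 when adjusted over the list alone), with Nrarp (1.79), Dtx1 (1.46) and Heyl (1.45) higher (camera adjusted p = 7.13e-06, and adjusted p = 0.0739 with an estimated correlation). Pre-TCR genes rose in 2 of 6 cases, Ptcra (1.94) and the recombinase gene Rag2 (1.40), while Dntt fell (-1.09), a call that becomes adjusted p = 0.0739 with an estimated correlation. Rag2 is below background in both DN2 (3.67) and DN3 (5.07). With the filter on low values the pre-TCR list does not pass by camera (adjusted p = 0.199). T lineage genes rose in 2 of 21, Cd5 (1.38) and Cd6 (1.19), both surface receptors of T cells, and Prkcq fell (-0.71), 6 higher and 2 lower when adjusted over the list alone, with camera adjusted p = 0.0148 and adjusted p = 0.211 with an estimated correlation. NPM-ALK and STAT3 linked genes fell in 6 of 29 cases, among them Socs1 (-0.89) and Gzmb (-0.73), and rose in 1, Icos (2.18), 10 lower and 5 higher when adjusted over the list alone, with camera adjusted p = 0.038 and adjusted p = 0.0929 with an estimated correlation. Gzmb is below background in both DN2 (4.90) and DN3 (4.16). With the filter on low values this list does not pass by camera (adjusted p = 0.133). Single members of lists that do not pass also moved, with Mrc1 (-2.37), H2-Ab1 (-1.74), Eng (-1.36) and Cd69 (-0.95) lower and Col1a2 (1.22) higher. Lists not passing had adjusted p from 0.0593 (cell cycle) to 0.939 (cytotoxic), and with the replicate block the cell cycle list passes as lower (adjusted p = 0.0269, against adjusted p = 0.711 with an estimated correlation and no block), and so do Usp18 (-0.88) and Lcn2 (-0.55). Median and mean differ in sign for the sort markers and for the activation, p53, interferon and cytotoxic genes.

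DN3 and DN4 differ in a single called gene, Il2ra (probe set 17366992, chromosome 2), a sort marker that is 9.92-fold lower in DN4 (log2 -3.31, SE 0.147, adjusted p = 1.48e-09). Limma called 1 gene where 659 passed unadjusted, and without DN3 array 1 it called 2. The count comes from the model without the replicate block, although DN3 and DN4 were taken as paired by number. That model pools the spread of all lymphoma fractions. CLP has the largest median SD over genes (0.235, against 0.156 in DN3 and 0.143 in DN4). Small differences between DN3 and DN4 can thus be missed, and a single call does not show that they are alike. No overlap was seen in 11.5% of genes, against 10% by chance. Cell cycle genes are lower as a list, with a median of -0.39 over 26 genes and camera adjusted p = 1.49e-16, though 0 pass one by one (1 when adjusted over the list alone) and the call becomes adjusted p = 0.204 with an estimated correlation. Interferon response genes are lower by camera (adjusted p = 0.0465, and adjusted p = 0.204 with an estimated correlation), with 0 of 14 passing one by one, and the call is lost with the replicate block (adjusted p = 0.0609). The other lists of genes outside the sort markers do not pass.

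Over the whole span from DN1 to DN4 the exchange is widest. Moxd1 is lower in DN4 (log2 -6.93, SE 0.304, adjusted p = 1.49e-10), followed by Pcsk1 (probe set 17288677, chromosome 13; -5.97), S100a6 (probe set 17399812, chromosome 3; -4.88), Lgals1 (probe set 17312829, chromosome 15; -4.66), Ly6c1 (-4.59), Jchain (-4.52), Igfbp4 (probe set 17256264, chromosome 11; -4.26) and Tgm2 (-3.93). Atp8a2 (4.43), Pde9a (4.42, SE 0.185, adjusted p = 1.05e-10), Susd4 (4.24), Fbp1 (probe set 17293557, chromosome 13; 4.22), Rhobtb3 (4.14), Apol11b (3.95) and Lmcd1 (3.44) rose. Of 21 immunoglobulin segments 18 fell, with a median of -2.61. In all 1245 genes were called, 626 higher and 619 lower, 543 by at least 2-fold, with no overlap in 21.3% of genes against 10% by chance.

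Notch targets rose in 6 of 14 cases and fell in 1 (8 and 1 when adjusted over the list alone), with Dtx1 (2.84), Notch3 (2.65) and Heyl (2.43), and camera keeps the call (adjusted p = 8.94e-08, and adjusted p = 0.0107 with an estimated correlation). Pre-TCR genes rose in 3 of 6, Ptcra by 9.05-fold (log2 3.18, SE 0.163), Rag2 by 1.66 and Arpp21 by 1.61, and Dntt fell (-1.07; 4 higher and 1 lower when adjusted over the list alone), with adjusted p = 0.0109 with an estimated correlation. Rag2 stays within the background range in DN4 (5.46). T lineage genes rose in 6 of 21, such as Cd5 (1.74), Cd6 (1.56) and Lef1 (1.43), and fell in 2, Txk (-1.58) among them (9 and 4 when adjusted over the list alone; camera adjusted p = 0.0147, and adjusted p = 0.189 with an estimated correlation). MHC class II genes fell in 4 of 8 cases, with H2-Ab1 5.27-fold (log2 -2.40), H2-Aa (-1.36) and H2-Eb1 (-0.95), and rose in 1 (adjusted p = 0.0107 with an estimated correlation). NPM-ALK and STAT3 linked genes fell in 7 of 29 cases and rose in 2 (10 and 4 when adjusted over the list alone), with Bcl3 (-1.74), Socs1 (-1.53), a feedback inhibitor of JAK and STAT signalling, and the kinase gene Pim1 (-1.05) lower and Icos (1.85) higher (adjusted p = 0.0107 with an estimated correlation).

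Cell cycle genes rose from DN1 to DN4 in 2 of 26 cases, Mcm5 (0.94) and Mcm2 (0.78), and 5 when adjusted over the list alone (camera adjusted p = 0.0115, and adjusted p = 0.534 with an estimated correlation). With the replicate block Tyms (0.52) and Rrm2 (0.48) pass as well. Granulocyte markers fell in 3 of 15, with Lcn2 (-1.34) and Itgam (-0.88), cytotoxic genes in 2 of 17, Ctsw (-1.23) and Klrd1 (-0.99), macrophage markers in 2 of 15, with Mrc1 (-2.54), and p53 targets in 2 of 15, with Foxo1 (-0.75; 3 when adjusted over the list alone). These 4 calls become adjusted p = 0.235, 0.181, 0.154 and 0.181 with an estimated correlation. Klrd1 is below background in both DN1 (4.90) and DN4 (3.91). In lists that do not pass (adjusted p = 0.107 to 0.805), Cd69 (-1.82), Pdcd1 (-1.14), Usp18 (-1.13), Oas2 (-0.96) and the glucose transporter gene Slc2a1 (-0.97) fell while Slc2a3 (1.27) and Ndrg1 (1.90) rose. Median, mean and test differ in sign for the stem, glycolysis and stromal lists.

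The CLP fraction against the mean of DN1 to DN4 shows small differences over many genes. Pde9a is higher by log2 2.59 (SE 0.146, adjusted p = 3.54e-08), at 9.92 in CLP, 9.39 in DN3 and 9.48 in DN4 but near background in DN1 (5.06) and DN2 (5.41). Also higher are Cpa3, a mast cell protease (probe set 17404337, chromosome 3; 1.94), H2bc9 (1.64), Adssl1 (1.27), Ociad2 (1.16), the interferon-induced gene Ifitm1 (1.02), H2-Oa (0.87) and Nkg7 (0.81). Ddx5 (probe set 17270999, chromosome 11), an RNA helicase, is 8.24-fold lower (log2 -3.04, SE 0.323, adjusted p = 6.95e-05), at 7.9, 5.81 and 7.87 in the CLP arrays. Mrc1 (-1.36), Zfp709 (-1.32), Zxda (-1.18), Pfkp (-0.85), the costimulatory receptor gene Cd28 (-0.72) and Themis (-0.61) are lower. Like Pde9a, Mrc1 and H2-Oa also differ among the DN fractions. Mrc1 is at 7.87 in DN1 and 7.47 in DN2, and is lower in DN3 than in DN2 and in DN4 than in DN1. H2-Oa is at 9.69 in CLP, 9.34 in DN3 and 9.205 in DN4, against 8.27 in DN1 and 8.45 in DN2. Of 984 called genes 334 are higher and 650 lower, and 99 differ at least 2-fold (4115 unadjusted). The number is 1939 without CLP array 1 and 609 without CLP array 2, and quantile normalization gives 446 higher and 415 lower of 861.

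Among lists, cell cycle genes were higher in CLP in 3 of 26 cases (6 when adjusted over the list alone; camera adjusted p = 0.00611, and adjusted p = 0.566 with an estimated correlation), and sort markers lower in 5 of 7. All other lists had adjusted p from 0.184 to 0.787, with for example 2 Notch targets higher and 1 lower and 1 MHC class II gene higher and 2 lower. The Notch target Dtx1 is not higher in CLP with the mean of its probe sets (log2 -0.058, adjusted p = 0.878 by limma). On an axis that runs from 0 at DN1 to 1 at DN4 over the 1245 genes called between these, CLP lies at 0.796 (SD 0.015, n = 3), DN2 at 0.368 (SD 0.017), DN3 at 0.973 (SD 0.013) and LSK at 0.206 (SD 0.033).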

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

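The counts of opposite directions below follow a rule written before the files were read, and the tests for named explanations appear in the last part of the text. Some genes moved in opposite directions against LSK in a pair of fractions, and their direct contrast passed: 2 for DN2 and DN1 (Iglv1 at -1.37 and 4.81, Il18r1 at -0.55 and 1.09), 22 for DN3 and DN2 (Rhobtb3 at 1.51 and -2.51, Pde9a at 2.79 and -1.19, Vim at -0.91 and 1.25), 1 for DN4 and DN3 (the sort marker Il2ra) and 63 for DN4 and DN1 (Lgals1 at -3.51 and 1.15, Igfbp4 at -1.40 and 2.85, Ly6c2 at -2.97 and 0.70, Ifitm3 at -2.36 and 1.23). The direct contrasts are the only test made of them, and their cause was not tested.

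Probe sets without a single gene symbol were left out of the gene tests, but 1388 of these 17824 passed between all lymphoma fractions and LSK (784 higher, 604 lower). The largest were probe sets 17290850 (8.19), 17466319 (7.55), 17399858 (-5.82) and 17459309 (-7.85). What they measure is not given in the sources used here and was not tested.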

How the results depend on the processing

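The settings here were chosen before the data were examined, except where said. Calls of the named genes mostly held under a trended and robust prior (1074 same, 7 weaker, 2 stronger), quantile normalization (1069 same, 7 weaker, 7 stronger) and a replicate block (1065 same, 2 weaker, 16 stronger), and 321 weakened when 1 array was left out (7723 same, 47 stronger). The named genes were mostly picked for large changes or small p, so these tallies say little of the other genes. CLP against LSK gave 3928 genes, 6140 with all 18 arrays in 1 model, and 2559 (without LSK 1) to 4598 (without CLP 1). CLP against the DN mean gave 984, and 609 (without CLP 2) to 1939 (without CLP 1). DN2 against DN1 gave 300, and 144 (without DN2 2) to 264 (without DN1 2), and DN4 against DN3 gave 1 to 2. With the mean of probe sets Dtx1 turned from 0.74 to -0.058 (CLP against DN mean, adjusted p = 0.878 by limma) and Ighm to -0.102 (DN3 against DN2). Of 93 list calls by camera 24 held and 69 were lost with an estimated correlation, and 75 held with the filter on low values. Alternatives chosen after the data were seen gave 6168 to 6396 genes without 1 fraction, 6239 without X and Y genes, and 1897 for the F test without CLP. Where not every same-number pair correlated over 0.1, as for DN1 with DN2 (0.04 to 0.334), CLP with the others, and all with LSK (3 of 15 pairs over 0.1), the arrays were taken to share only a number. There the replicate block gave 394 genes for DN2 against DN1, 1259 for CLP against the DN mean, 2036 for the F test and 6342 for all fractions against LSK. Over all fractions 11 of 15 arrays correlate best with their own number, a hint from the data and not from the design. In the comparisons named as paired the block changed no other camera call, and no other call of a named gene, than those given with the results. How many genes over all pass with the block in these comparisons is not given here. By fry these lists pass only with the block: B cell markers from DN2 to DN3 (adjusted p 0.0628 to 0.0353), and from DN3 to DN4 Notch (0.0559 to 0.0177), STAT3 (0.0519 to 0.00169), cell cycle (0.169 to 0.0413) and MHC class II genes (0.202 to 0.041). The Notch and STAT3 lists hold the sort marker Il2ra, the only gene called from DN3 to DN4. By camera neither list passes there with Il2ra (adjusted p = 0.195 and 0.388) or without it (adjusted p = 0.996). Camera thus cannot tell whether Il2ra carries the fry calls. From DN3 to DN4 the Notch list has a mean of -0.227 and a median of -0.027, and the STAT3 list -0.132 and -0.029. With Il2ra at -3.31, the fall of both list means lies mostly in this sort gene. No fry result without Il2ra is given here. Leaving the sort marker genes out of the Notch and STAT3 lists, chosen after the data were seen, kept all 14 calls of these lists and added 1. Why a setting moved a count was not studied, and the cause was not tested. Signals near background limit what can be said of weakly expressed genes.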

Other observations

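Tests of the immunoglobulin pattern, of a single RNA pool and of CLP against each DN fraction were chosen after the result was seen, and the other tests were written before. Each comparison of 3 arrays with 3 has 10 splits, which cannot give a share under 0.05. The real grouping was the only 1 of 10 with its number of calls, and the highest other gave 0, for all fractions against LSK (6425), CLP (3928), DN1 (4378), DN2 (5638), DN3 (5443) and DN4 (5908) against LSK, DN2 against DN1 (300), DN3 against DN2 (544), DN4 against DN3 (1) and DN4 against DN1 (1245). The splits that part as many same-number pairs as the real grouping are among those with 0. Among 100 labelings of the fractions the F test gave 1748 for the real 1 and at most 234 for any other, so chance does not explain a difference among the fractions. CLP against the DN mean gave 984 and at most 44. Labelings of all fractions do not test CLP apart from the differences among DN1 to DN4.

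The immunoglobulin signal is highest in DN1 among the lymphoma fractions, with a kappa variable segment of the Igkv9 family at 10.73 (SD 0.067, n = 3) and Iglv1 at 10.15. In DN2 the arrays split, with the same segment at 3.38, 10.37 and 10.18, and in DN3, DN4 and CLP it is below background. The signal is not confined to DN1, since Ighm stays at 10.63 to 11.51 in the other fractions and 12.25 in LSK, and LSK arrays read 10.81, 8.05 and 3.76 for the kappa segment. Of 21 immunoglobulin segments 3 are higher in DN1 than in LSK.

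For this signal, B cells in the DN1 gate may be the source, though the sort used lineage markers (not named in the sources used here) that normally remove B and myeloid cells. The other B cell markers differ by a median of 0.154 between DN1 and DN2, against 2.45 for the immunoglobulin segments, but 3 of 13 are above background in DN1, so this stays open. Plasma cells in the DN1 gate could also carry it, and of 16 plasma cell markers 0 are higher in DN1 (Xbp1 differs by 0.68, adjusted p = 0.0527 by limma), which leaves the question open, since antibody transcripts exceed such markers by far in few cells. Myeloid or dendritic cells carried into the DN1 gate stay open too, with 4.76% of their markers higher in DN1 and 15 of 42 above background there. A count of antibody-positive cells in the gate would settle it.

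Replicate arrays of DN2, DN3 and DN4 differ little, and if arrays of a fraction were taken from 1 lymphoma, few probe sets should range by over 2 log2 units. The counts are 97, 222 and 182, against 190 in LSK, 395 in DN1 and 2160 in CLP, so 222 at most leaves this possible. Arrays of a fraction taken from 1 pool of RNA should share no replicate number that stands apart, unless a technical batch follows the numbers. Yet 8 probe sets show the same number apart in all of DN2, DN3 and DN4, against 4 at most in any other of 36 arrangements of the numbers. That argues against a pool, though such a batch stays open. Probe sets 17550689, 17550693, 17551089 and 17551097 move together over the arrays, so the 8 are not independent. If the numbers stand for 3 lymphomas with differing private genes, the mean over the 5 fractions should differ between numbers, and it does by over 2 log2 units in 18 probe sets, though not in every fraction of each, which is too little to decide. Viral integration sites per array would tell.

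CLP arrays lie between DN2 and DN3 on the DN1 to DN4 axis, nearer to DN3, which cells of the DN fractions making up the CLP gate could cause. Of the axis genes 0.643% lie outside the DN range in CLP by over 0.5 log2 units. Such a mixture or a separate intermediate population predicts a low share. However, these genes were picked because DN1 and DN4 differ, which makes their DN range wide. A low share was thus likely in advance and cannot tell what CLP is. Over all genes 6 are called above and 39 below each of the 4 DN fractions, which a mixture alone does not give but a technical shift of the CLP arrays could, so the mixture stays open. Low RNA input or integrity in the CLP arrays may add to this, and 6.24% of small RNA genes were called against 4.39% of others, which leaves it open. A test would be sorting CLP again by IL7Rα with matched cell numbers.

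Compared with each fraction, CLP differs in 1726 genes from DN1, 636 from DN2, 243 from DN3 and 237 from DN4.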
